A study of Homo sapiens with 8 samples.

How the data were processed

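RNA was sequenced from 8 libraries of H9 cells, an established human embryonic stem cell line, made with a stranded mRNA kit. The libraries formed 4 groups of 2 biological replicates each. UD cells were undifferentiated. E24 cells had been synchronised with 100 ng/ml nocodazole for 16 h, released, and taken through mesendoderm differentiation for 24 h in medium with activin, BMP, LY294002 (a PI3 kinase inhibitor), CHIR99021 (a GSK3 inhibitor that activates WNT signalling) and insulin. E24HU and E24Noc cells were synchronised in the same way and differentiated for the same 24 h. E24HU cells received hydroxyurea, which blocks DNA synthesis in S phase, from 0 h of differentiation. E24Noc cells received nocodazole, which depolymerises microtubules and arrests cells in mitosis, from 8 h. The labels do not say whether UD cells were synchronised.

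The deposited table held raw read counts per gene, made by the authors from sorted alignments, and the submitters' processing notes name the GRCh38 genome build and DESeq2. The counting program, its strand setting and its handling of reads that match several genes are not given in the sources used here, so no statement rests on the strand of a read, and values of close paralogs (tubulins, histones, actins) carry that limit. The deposited annotation (GENCODE 21) was used for positions and gene types alone, and 19172 gene IDs were placed in it. The table listed 21853 lines for 19231 NCBI gene IDs, because 1173 IDs stood on more than 1 line with the same counts, and each ID was used once. A total of 1225 IDs had no read in any library. Library totals ran from 74.31 to 93.21 M reads, and mitochondrial mRNAs took 9.584% to 11.836% of them.

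Differential expression was tested on the counts with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by group) in R 4.3.3, with all 8 libraries in 1 fit and 1 coefficient per group. After the filter, 15681 genes were tested in each of 6 comparisons, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as CPM (read counts per M reads of the TMM-scaled library size) with the SD between both libraries of a group (n = 2). Genes with 3 reads or fewer in a group are given as levels and not as folds. Per comparison, the named genes were the 6 largest increases and decreases among protein-coding genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, the members of each list with the smallest p, and a fixed set of fate and cell cycle genes. Some genes withheld for evaluation are not described. In total 22 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives, except those named below as added. The lists were pluripotency, primitive streak, definitive endoderm, early mesoderm, neuroectoderm, trophectoderm and amnion, G1/S and DNA replication, G2/M and mitosis, p53 targets, core histones and H1, tubulins, WNT targets, BMP targets, activin and NODAL targets, FOXO targets, integrated stress and unfolded protein response, hypoxia and glycolysis, immediate early genes, cholesterol synthesis, epithelial, mesenchymal, and mitochondrially encoded mRNAs. Some genes stood on more than 1 list, so the list results are not independent of each other. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation.

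The labels give no shared day or batch for a replicate number. Before any calls were compared, the deviations of same-numbered libraries from their group means were correlated across genes for each of the 6 pairs of groups. All 6 correlations were above 0.1: 0.208 to 0.244 between UD and the differentiated groups, and 0.535, 0.546 and 0.655 among the differentiated groups. The numbers were therefore taken to pair the libraries, on the evidence of the data and not of the labels, and a fit with the replicate number as a block is given beside a result where it changed a call or moved a count by more than 1.5 times. The block assumes the same replicate difference in all 4 groups. The weaker correlations with UD speak against that, as do BMP targets. Their median log2 difference, number 2 minus number 1, was -0.193 in UD, 0.543 in E24, 1.552 in E24HU and 0.163 in E24Noc. Calls with the block carry this limit. Genes named from the blocked fit alone were chosen after their values were seen.

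The tests were tried on simulated counts for E24HU against E24, drawn with the spread of these libraries and with a replicate effect (5 runs, 15557 genes). The fit without a block found 48 of 100 genes changed by 2-fold and 86 of 100 changed by 4-fold, and 0.45% of its calls were false. The blocked fit found 82 of 100 and 100 of 100, and 9.66% of its calls were false, more than the threshold allows. In counts drawn without a replicate effect the fit without a block found 63 and 95 of 100 with 7.07% of its calls false, and the blocked fit 60 and 95 with 8.1%. Comparisons against the same E24 libraries share their noise, so counts of genes in both were set against 20 simulations in which E24HU and E24Noc did not differ from E24. Groups of 2 libraries are too small for a permutation test of a single gene to pass any usual threshold.

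Alternatives were RLE size factors, library size alone, no filter on low counts, a stricter filter (10 reads in each library of a group and a mean of 1 CPM), protein-coding genes only, DESeq2 1.42.0, limma-voom, the compared groups alone, the replicate block, and leaving out each library. DESeq2 with the block, the block without the UD libraries and the block with an estimated correlation were added after the data were examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.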

Results

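Gene expression was measured by RNA sequencing in 8 libraries of H9 human embryonic stem cells, 2 for each of 4 groups. These were undifferentiated cells (UD), cells after 24 h of mesendoderm differentiation (E24), and cells differentiated for the same time under an S phase block with hydroxyurea (E24HU) or a mitotic block with nocodazole (E24Noc). The series asks how the position of cells in the cell cycle bears on their differentiation. Library totals, in M reads, were 76.14 and 93.21 in UD, 74.31 and 80.39 in E24, 85.76 and 75.02 in E24HU, and 87.45 and 81.03 in E24Noc. The first principal component held 63.55% of the variance and parted UD (-93.2 and -86.95) from the differentiated libraries (8.19 to 45.53). The second, with 12.87%, placed E24HU (43.95 and 22.84) and E24Noc (-18.04 and -38.41) on opposite sides of E24 (10.06 and -8.75). All positions below are on GRCh38.

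Differentiation for 24 h induced primitive streak genes. TBXT, the T-box factor that marks the streak and nascent mesoderm (chromosome 6, 166157656 to 166168700), stood at 421 ± 159 CPM (SD, n = 2) in E24 and 3.0 ± 3.05 CPM in UD, 142-fold higher (log2 fold change 7.15, SE 0.97, adjusted p = 0.00351). MIXL1, a homeobox gene of the same stage (chromosome 1, 226223618 to 226227054), rose 129-fold to 1501 ± 663 CPM (SE 1.11, adjusted p = 0.0056), and EVX1 rose 333-fold to 260.6 ± 1.69 CPM (SE 0.48, adjusted p = 0.000315). SOX2, a factor of the pluripotent and neural states (chromosome 3, 181711924 to 181714436), dropped from 361.7 ± 7.52 to 59.87 ± 4.74 CPM (log2 fold change -2.59, SE 0.22, adjusted p = 0.000895). MSGN1, a gene of presomitic mesoderm, had 0 and 2 reads in the UD libraries and 975 and 579 in E24.

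By list, 15 of 18 primitive streak genes rose and 0 fell (15 and 0 adjusted over the list alone; list adjusted p = 1.04e-13, and adjusted p = 0.318 with an estimated correlation). NKX1-2 (log2 fold change 2.88) and SP5 (4.13) were among them. The libraries numbered 1 had higher primitive streak levels than those numbered 2 in all 4 groups, with a median log2 difference of 1.327 in UD, 0.798 in E24, 0.809 in E24HU and 1.305 in E24Noc. Of 21 pluripotency genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone; list adjusted p = 8.02e-13, and adjusted p = 0.318 with an estimated correlation). PRDM14, a repressor of differentiation, fell by 4.14 on the log2 scale, while POU5F1 (OCT4) fell by 0.85 and stayed at 507 ± 111 CPM. NANOG fell by 2.01. Early mesoderm genes rose in 13 cases and fell in 2 of 22 (14 and 2 adjusted over the list alone; list adjusted p = 2.28e-06, and adjusted p = 0.238 with an estimated correlation). MSX1 rose by 5.97 and FOXC1 by 1.75. Definitive endoderm genes went both ways, 4 of 15 up and 3 down (4 and 3 adjusted over the list alone; list adjusted p = 0.477). With the replicate block 5 rose and 5 fell. GATA4 (5.3) and GATA6 (5.06) rose. SOX17, the endoderm factor, was at 0.942 ± 0.845 CPM against 1.51 ± 1.68 in UD (adjusted p = 0.703). Neuroectoderm genes fell in 10 cases and rose in 2 of 18 (12 and 2 adjusted over the list alone; list adjusted p = 3.48e-05, and adjusted p = 0.318 with an estimated correlation). SIX3 fell by 2.04 and POU3F1 by 2.1.

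Markers of other lineages and of cell shape moved as well. Of 12 trophectoderm and amnion genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone; list adjusted p = 0.17). CDX2, which marks trophectoderm and also the posterior streak, rose 250-fold to 70.5 ± 14.2 CPM, and KRT7 fell by 4.11. With the block 7 of these genes rose and 3 fell, and the list passed as higher without E24HU replicate 1 (0.039) or 2 (0.0396). Epithelial genes fell in 13 of 19 cases and rose in 0 (14 and 0 adjusted over the list alone; list adjusted p = 3.39e-08, and adjusted p = 0.318 with an estimated correlation). The tight junction gene CLDN3 (-3.19) and the splicing factor ESRP2 (-1.87) were among them. Mesenchymal genes rose in 12 cases and fell in 2 of 17 (13 and 2 adjusted over the list alone; list adjusted p = 9.46e-07, and adjusted p = 0.384 with an estimated correlation). VIM, the intermediate filament vimentin, rose by 2.01, ZEB1 by 1.34 and CDH2 (N-cadherin) by 0.97.

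Targets of the pathways that the medium activates were higher. WNT targets rose in 13 cases and fell in 1 of 17 (14 and 2 adjusted over the list alone; list adjusted p = 2.38e-19, and adjusted p = 0.238 with an estimated correlation). The WNT antagonists DKK1 (log2 fold change 6.34, SE 0.28, adjusted p = 0.000151) and NKD1 (5.12, SE 0.39, adjusted p = 0.000627) rose. BMP targets rose in 11 cases and fell in 1 of 17 (12 and 1 adjusted over the list alone; list adjusted p = 4.78e-07, and adjusted p = 0.413 with an estimated correlation). The pathway inhibitors NOG (3.43) and BAMBI (3.13) rose. Activin and NODAL targets rose in 8 cases and fell in 1 of 14 (8 and 2 adjusted over the list alone; list adjusted p = 0.000317, and adjusted p = 0.413 with an estimated correlation). SMAD7, an inhibitor of the pathway, rose by 1.47, and 3 genes fell with the block. GSC rose by 3.97 (adjusted p = 0.0101, and 0.0668 and 0.0578 without UD replicate 1 and 2). FOXO targets, relevant to the PI3 kinase inhibitor, rose in 3 cases and fell in 3 of 12 (3 and 4 adjusted over the list alone; list adjusted p = 0.654). TXNIP rose by 2.33 and CITED2 fell by 1.14, and 5 genes fell with the block.

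Proliferation genes were lower and p53 targets higher in E24 than in UD. E24 cells had been synchronised with nocodazole and released, and E24HU and E24Noc cells had the same synchronisation. The labels do not say whether UD cells were synchronised. These and other differences from UD may therefore include an effect of the synchronisation. Of 54 G2/M and mitosis genes, 30 fell and 0 rose (35 and 0 adjusted over the list alone; list adjusted p = 1.01e-08, and adjusted p = 0.455 with an estimated correlation). PLK1, the mitotic kinase (-0.85), and PIMREG (-1.29) were among them. Of 47 G1/S and DNA replication genes, 26 fell and 0 rose (29 and 0 adjusted over the list alone; list adjusted p = 1.1e-06, and adjusted p = 0.5 with an estimated correlation). The primase subunit PRIM1 fell by 1.2 and the helicase subunit MCM2 by 0.75. CCNE2 was at 9.04 ± 0.587 CPM against 6.87 ± 0.0497 (adjusted p = 0.132), and CCNE1 at 41.97 ± 10.6 against 55.31 ± 6.86 (adjusted p = 0.223). Of 32 p53 targets, 22 rose and 0 fell (25 and 0 adjusted over the list alone; list adjusted p = 2.25e-11, and adjusted p = 0.413 with an estimated correlation). CDKN1A, the CDK inhibitor p21 (chromosome 6, 36676460 to 36687339), rose 7.83-fold to 274.2 ± 134 CPM (SE 0.47, adjusted p = 0.00564), BTG2 rose by 3.02 and GDF15 by 2.58.

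Of the remaining lists, immediate early genes rose in 5 cases and fell in 0 of 17 (5 and 0 adjusted over the list alone; list adjusted p = 0.0331, and adjusted p = 0.482 with an estimated correlation). JUNB rose by 2.07, and with the block 7 of the 17 genes rose and 2 fell. The list call was lost with the replicate block (adjusted p = 0.0936), without UD replicate 2 (0.0563) and without E24 replicate 2 (0.073). Integrated stress and unfolded protein response genes rose in 6 cases and fell in 2 of 19 (6 and 2 adjusted over the list alone; list adjusted p = 0.124). DDIT4, an inhibitor of mTORC1, rose by 2.79, and the list passed without E24 replicate 1 (0.041). Hypoxia and glycolysis genes rose in 3 cases and fell in 5 of 19 (4 and 5 adjusted over the list alone; list adjusted p = 0.786), and with the block 7 rose. Their median was 0.079, their mean -0.149 and their median under scaling by library size -0.004. ADM (-2.18) and the hexokinase gene HK2 (-0.97) fell. Cholesterol synthesis genes rose in 2 cases and fell in 3 of 22 (2 and 3 adjusted over the list alone; list adjusted p = 0.477), and 5 fell with the block. Their median was 0.016, their mean -0.098 and their median under scaling by library size -0.061. Tubulins rose in 2 cases and fell in 3 of 12 (2 and 4 adjusted over the list alone; list adjusted p = 0.425), with TUBB4A at -2.18. Core histones and H1 rose in 2 cases and fell in 0 of 14 (0 and 0 adjusted over the list alone; list adjusted p = 0.0847), with 6 higher under the block. The list passed without E24 replicate 1 (0.0378), without E24HU replicate 1 (0.039) or 2 (0.0396), and under scaling by library size (0.0499). Mitochondrially encoded mRNAs rose in 1 case and fell in 0 of 13 (0 and 0 adjusted over the list alone; list adjusted p = 0.0506). With the block 10 rose (list adjusted p = 0.0378, and adjusted p = 0.654 with an estimated correlation). Without 1 of 5 libraries (E24 replicate 1, E24HU replicate 1 or 2, E24Noc replicate 1 or 2) the list passed with 0.0286 to 0.0396.

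In all, 4906 of 15681 genes differed between E24 and UD (2403 higher, 2503 lower), and 2275 of them by at least 2-fold (862 higher, 1413 lower). Scaling by library size alone gave 1955 higher and 2739 lower. The count was 2039 without UD replicate 1, 3009 without UD replicate 2 and 1300 without E24 replicate 2, where a lone library was assumed to vary like the other groups. Among the genes given here, leaving out 1 library ended the call of POU5F1 (adjusted p = 0.151 without UD replicate 1, 0.0706 without UD replicate 2, 0.187 without E24 replicate 2), NANOG (0.0945 without UD replicate 1, 0.102 without E24 replicate 2) and MCM2 (0.0622 without E24 replicate 2).

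**Figure D1:**
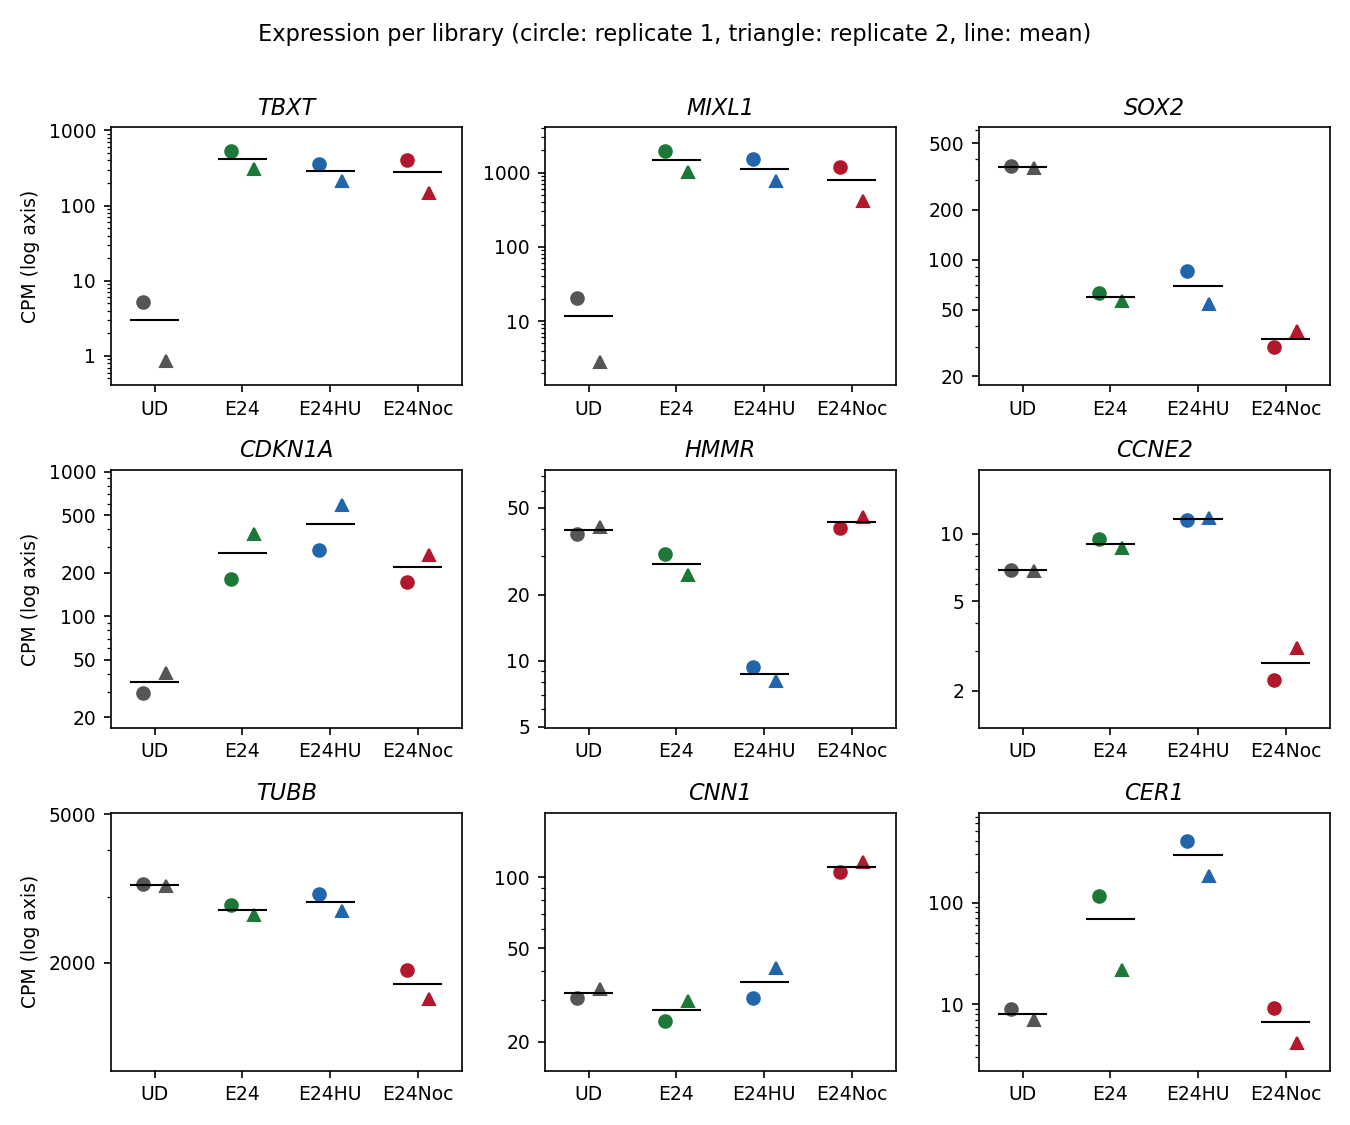
Expression of 9 genes in each of the 8 libraries, in CPM on a log axis, with circles for libraries numbered 1, triangles for libraries numbered 2, and a line at the mean of each group. TBXT and MIXL1 lie far above UD in the 3 differentiated groups, HMMR is lowest in E24HU (8.69 CPM on average), and TUBB and CCNE2 are lowest in E24Noc (1757 and 2.65 CPM).

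Hydroxyurea, given to ask what an S phase block does to differentiating cells, lowered mitotic genes. HMMR, a spindle assembly factor (chromosome 5, 163460203 to 163491945), dropped from 27.78 ± 4.23 CPM in E24 to 8.69 ± 0.886 in E24HU, a 3.2-fold decrease (log2 fold change -1.68, SE 0.15, n = 2, adjusted p = 0.0347). PLK1 (chromosome 16, 23677656 to 23690367) was 2.43-fold lower (-1.28, SE 0.12), and the mitotic kinesins KIF20A (-1.41, SE 0.13; chromosome 5, 138178719 to 138187715) and KIF4A (-0.84, SE 0.09; chromosome X, 70290090 to 70420832) fell too. NTS, which encodes the peptide neurotensin (chromosome 12, 85874295 to 85882992), fell by 1.62, and TMEM179 (chromosome 14, 104474678 to 104605647) rose by 2.37, from 2.1 ± 0.173 to 10.83 ± 2.47 CPM.

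Of 54 G2/M and mitosis genes, edgeR called 2 lower and 0 higher over all genes tested, 39 and 0 adjusted over the list alone, and 29 and 0 with the replicate block. At an unadjusted p under 0.05, 39 were lower and 0 higher, and DESeq2 called 29 and 0 and limma-voom 2 and 0. Their median was -0.588 (list adjusted p = 5.44e-55, and adjusted p = 0.26 with an estimated correlation). G1/S and DNA replication genes went both ways (median 0.038, mean -0.05, list adjusted p = 0.519). The list passed as lower without E24 replicate 2 (0.000829) and without E24HU replicate 1 (0.00142). With the block, 1 rose and 4 fell (1 and 3 adjusted over the list alone without it). RRM2, the ribonucleotide reductase subunit whose enzyme hydroxyurea inhibits, was the 1 higher (0.59, adjusted p = 0.0193 with the block and 0.125 without). Hypoxia and glycolysis genes were higher as a list (median 0.521, list adjusted p = 2.23e-06, and adjusted p = 0.26 with an estimated correlation). Of 19, edgeR called 0 over all genes (8 higher and 1 lower unadjusted, DESeq2 3 higher, limma-voom 0), and 6 were higher adjusted over the list alone, and 3 higher and 1 lower with the block. SLC2A1, the glucose transporter GLUT1, was at 524.3 ± 55.2 CPM against 274.7 ± 5.84 (adjusted p = 0.22, 0.0111 with DESeq2, 0.0748 with the block, and 0.000328 with the block without the UD libraries). Immediate early genes were higher as a list (median 0.698, list adjusted p = 1.35e-05, and adjusted p = 0.528 with an estimated correlation). Of 17, edgeR called 0 over all genes or over the list alone (5 higher unadjusted, DESeq2 1 higher, limma-voom 0) and 2 were higher with the block, ATF3 (1.04, adjusted p = 0.0154 with the block) and CTGF (1.15, adjusted p = 0.038 with the block).

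A further 4 lists passed, with and without the block, but not without some single libraries, and limma-voom called 0 of their genes. With the block the list adjusted p was 2.28e-07 to 0.035, and 0.44 to 0.621 with an estimated correlation too. Leaving out 1 library unbalances the replicate numbers, so a call that ends there may rest on that library or on the broken pairing. BMP targets were lower (median -0.552, list adjusted p = 0.00104, and adjusted p = 0.782 with an estimated correlation). Of 17, edgeR called 0 over all genes, the list alone or the block (1 lower unadjusted, DESeq2 0). The call ended without E24 replicate 2 (0.203) or E24HU replicate 1 (0.83, with the direction turned to higher). P53 targets were higher (median 0.23, list adjusted p = 0.00131, and adjusted p = 0.782 with an estimated correlation). Of 32, edgeR called 0 over all genes, 1 adjusted over the list alone and 3 with the block (1 higher and 1 lower unadjusted, DESeq2 1 higher). The call ended without E24 replicate 1 (0.64) or E24HU replicate 2 (0.581). GDF15 was the stress-induced cytokine among these 3 (1.19, adjusted p = 0.0123 with the block). Tubulins were higher (median 0.187, list adjusted p = 0.0261, and adjusted p = 0.617 with an estimated correlation). Of 12, edgeR called 0 over all genes, 1 adjusted over the list alone and 2 with the block (1 higher unadjusted, DESeq2 1 higher). The call ended without E24 replicate 2 (0.0708) or E24HU replicate 2 (0.0691). Core histones and H1 were lower (median -0.251, list adjusted p = 0.0261, and adjusted p = 0.782 with an estimated correlation). Of 14, edgeR called 0 over all genes, the list alone or the block (3 lower unadjusted, DESeq2 0). The call ended without E24 replicate 2 (0.292) or E24HU replicate 1 (0.993). With the block, integrated stress genes (list adjusted p = 0.037, and adjusted p = 0.454 with an estimated correlation) and mesenchymal genes (0.017, and adjusted p = 0.448 with an estimated correlation) were higher as well. Both also passed without E24 replicate 2 (0.0209 and 0.0112) or E24HU replicate 1 (0.00576 and 0.000899), and mesenchymal genes without E24Noc replicate 1 (0.033) or 2 (0.0333).

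Fate gene lists did not pass with all libraries: primitive streak (median -0.046, mean 0.007, list adjusted p = 0.796), early mesoderm (-0.158, 0.427), definitive endoderm (0.273, 0.247), neuroectoderm (0.044, 0.257), pluripotency (-0.138, 0.375), trophectoderm and amnion (-0.261, 0.272) and activin and NODAL targets (0.171, 0.504). TBXT was at 284.9 ± 98.6 CPM against 421 ± 159 in E24 (log2 fold change -0.56, adjusted p = 0.815, 0.375 with the block, and 0.0291 with the block without the UD libraries, a fit added after the data were seen) and SOX2 at 69.74 ± 21.7 against 59.87 ± 4.74 (adjusted p = 0.733). Definitive endoderm (0.0104), neuroectoderm (0.00516) and activin and NODAL targets (0.00664) passed as higher without E24 replicate 1. Definitive endoderm (0.0102) passed as higher, and early mesoderm (0.00105) and trophectoderm and amnion (0.00253) as lower, without E24HU replicate 2, and pluripotency as lower without E24 replicate 2 (0.0112) or E24HU replicate 1 (0.00688). With the block, genes chosen after their values were seen included CER1, a secreted NODAL and BMP inhibitor of anterior endoderm (294.1 ± 158 against 68.88 ± 66.8 CPM, log2 fold change 2.33, SE 0.39, adjusted p = 0.0285 with the block), which rose, and CDX2 (-1.98, SE 0.3, adjusted p = 0.0219 with the block) and the WNT agonist RSPO3 (-1.95, SE 0.28, adjusted p = 0.0187 with the block), which fell.

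Between E24HU and E24, 6 of 15681 genes passed (1 higher, 5 lower), 1931 had an unadjusted p under 0.05, and 468 passed with the replicate block (248 higher, 220 lower), the 6 among them. Leaving out any library ended all 6 calls (the count was 0 each time, with adjusted p from 0.0816 for HMMR without UD replicate 1 to 0.318 without E24 replicate 1), as did fitting the compared groups alone or scaling by library size alone.

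Nocodazole, given to ask what a mitotic block does, raised 2 genes of the contractile actin cytoskeleton. CNN1, the actin-binding protein calponin (chromosome 19, 11538717 to 11550323), rose 4.07-fold from 27.15 ± 3.83 CPM in E24 to 110.6 ± 7.55 in E24Noc (log2 fold change 2.03, SE 0.17, n = 2, adjusted p = 0.0337), and ACTA1, skeletal muscle actin (chromosome 1, 229431245 to 229434098), rose 4.04-fold to 17.09 ± 1.4 CPM (SE 0.18, adjusted p = 0.0337). EMX2, a forebrain homeobox gene (chromosome 10, 117542444 to 117549546), fell by 1.42 (SE 0.1, adjusted p = 0.028), and SPRY1, a feedback inhibitor of FGF signalling (chromosome 4, 123396795 to 123403760), fell by 1.85 (SE 0.18, adjusted p = 0.0442). CCNE2, cyclin E2 of the G1/S transition (chromosome 8, 94879770 to 94896678), was at 2.65 ± 0.609 CPM against 9.04 ± 0.587, and passed with the block (-1.78, SE 0.17, adjusted p = 0.0131 with the block and 0.0574 without).

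Of 54 G2/M and mitosis genes, edgeR called 0 over all genes (36 higher and 1 lower unadjusted, DESeq2 16 higher, limma-voom 0). In edgeR 32 were higher and 1 lower adjusted over the list alone, and 12 were higher and 0 lower with the block. Their median was 0.458 (list adjusted p = 7.65e-40, and adjusted p = 0.279 with an estimated correlation). Tubulins, the targets of the drug, were lower (median -0.196, list adjusted p = 9.89e-05, and adjusted p = 0.279 with an estimated correlation). Of 12, edgeR called 0 over all genes, 4 lower adjusted over the list alone and 4 lower with the block (4 lower unadjusted, DESeq2 4 lower, limma-voom 0). TUBB (chromosome 6, 30720201 to 30725426) was at 1757 ± 225 CPM against 2773 ± 117 (log2 fold change -0.66, SE 0.08, adjusted p = 0.0213 with the block), and TUBA1B at 1118 ± 176 against 1693 ± 152 (-0.6, SE 0.1, adjusted p = 0.0365 with the block). Epithelial genes were higher (median 0.28, list adjusted p = 2.23e-05, and adjusted p = 0.311 with an estimated correlation). Of 19, edgeR called 0 over all genes or with the block and 4 higher adjusted over the list alone (5 higher unadjusted, DESeq2 2 higher, limma-voom 0). Levels of tubulin and actin genes may mix reads of close paralogs.

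Mesendoderm lists were lower than in E24, and limma-voom called 0 of their genes. These lists share members, so their results are not separate evidence. GSC stood on the activin and NODAL and the primitive streak lists, and CER1 on the activin and NODAL and the definitive endoderm lists. Activin and NODAL targets had a median of -0.672 (list adjusted p = 2.46e-07, and adjusted p = 0.311 with an estimated correlation). Of 14, edgeR called 0 over all genes, 5 lower adjusted over the list alone and 4 lower with the block (6 lower unadjusted, DESeq2 3 lower). Definitive endoderm genes had a median of -0.829 (list adjusted p = 2.65e-05, and adjusted p = 0.311 with an estimated correlation). Of 15, edgeR called 0 over all genes, 3 lower adjusted over the list alone and 5 lower with the block (4 lower unadjusted, DESeq2 2 lower). Early mesoderm genes had a median of -0.489 (list adjusted p = 3.15e-06, and adjusted p = 0.279 with an estimated correlation). Of 22, edgeR called 0 over all genes, 1 lower adjusted over the list alone and 6 lower with the block (7 lower unadjusted, DESeq2 3 lower). Primitive streak genes had a median of -0.68 (list adjusted p = 0.000262, and adjusted p = 0.533 with an estimated correlation). Of 18, edgeR called 0 over all genes or over the list alone and 3 lower with the block (3 lower and 1 higher unadjusted, DESeq2 1 lower). The call ended without E24Noc replicate 2 (0.354). With the block, genes chosen after their values were seen were CER1 (6.66 ± 3.49 against 68.88 ± 66.8 CPM, log2 fold change -3.14, SE 0.42, adjusted p = 0.0238 with the block), GSC, a homeobox gene of the organiser (-2.61, SE 0.31, adjusted p = 0.0213 with the block), MSGN1 (-2.99, SE 0.38, adjusted p = 0.0238 with the block) and GATA6 (-2.23, SE 0.2, adjusted p = 0.00962 with the block), which fell. TBXT was at 277.3 ± 182 CPM (adjusted p = 0.915, and 0.343 with the block) and MIXL1 at 801.8 ± 552 CPM (adjusted p = 0.871, and 0.239 with the block). Both passed as lower with the block without the UD libraries (adjusted p = 0.0153 and 0.00146), a fit added after the data were seen.

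The remaining list calls each ended without some single library, which also unbalances the replicate numbers. With the block all of them but FOXO targets passed in the same direction (list adjusted p = 2.41e-06 to 0.00942). With the block and an estimated correlation these had an adjusted p of 0.229 to 0.554. G1/S genes were lower (median -0.144, list adjusted p = 9.7e-07, and adjusted p = 0.533 with an estimated correlation), but not without E24 replicate 1 (0.236), as was neuroectoderm (-0.452, list adjusted p = 0.000358, and adjusted p = 0.311 with an estimated correlation; 0.236 without E24 replicate 1). BMP targets were higher (median 0.451, list adjusted p = 0.0102, and adjusted p = 0.655 with an estimated correlation), but not without E24 replicate 1 (0.602) or E24Noc replicate 2 (0.0707). Mesenchymal genes were lower (median -0.177, list adjusted p = 0.00157, and adjusted p = 0.515 with an estimated correlation), but not without E24 replicate 2 (0.106) or E24Noc replicate 1 (0.555). P53 targets were lower (median -0.136, list adjusted p = 0.0293, and adjusted p = 0.761 with an estimated correlation), but the direction turned to higher without E24 replicate 2 (0.176) or E24Noc replicate 1 (0.884). Integrated stress genes were higher (median 0.137, list adjusted p = 0.028, and adjusted p = 0.428 with an estimated correlation), but not without E24 replicate 1 (0.351) or E24Noc replicate 1 (0.0714). FOXO targets were lower (median -0.149, list adjusted p = 0.0422, and adjusted p = 0.344 with an estimated correlation), but not with the block (0.0522), nor without UD replicate 1 (0.0659) or 2 (0.0636), E24 replicate 1 (0.0547) or 2 (0.106), or E24Noc replicate 1 (0.494). Without E24 replicate 1, 9 lists passed in place of 14. Trophectoderm and amnion genes (median 0.269, list adjusted p = 0.0726) passed as higher without E24 replicate 2 (0.0246), E24HU replicate 1 (0.00933) or 2 (0.0099) or E24Noc replicate 1 (0.0408), and under scaling by library size alone (0.0428), and pluripotency genes (-0.107, 0.516) as lower without E24 replicate 2 (0.00658) or E24Noc replicate 1 (0.0368). Core histones and H1 passed as lower without E24Noc replicate 2 (0.0418), and mitochondrially encoded mRNAs as higher without E24Noc replicate 1 (0.0475).

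Between E24Noc and E24, 4 of 15681 genes passed (2 higher, 2 lower), 1264 had an unadjusted p under 0.05, and 243 passed with the replicate block (99 higher, 144 lower), the 4 among them. All 4 calls ended without any 1 of the UD, E24 or E24Noc libraries (adjusted p from 0.064 for EMX2 without UD replicate 1 to 0.442 for SPRY1 without E24Noc replicate 1), and in a fit of the compared groups alone.

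**Figure D2:**
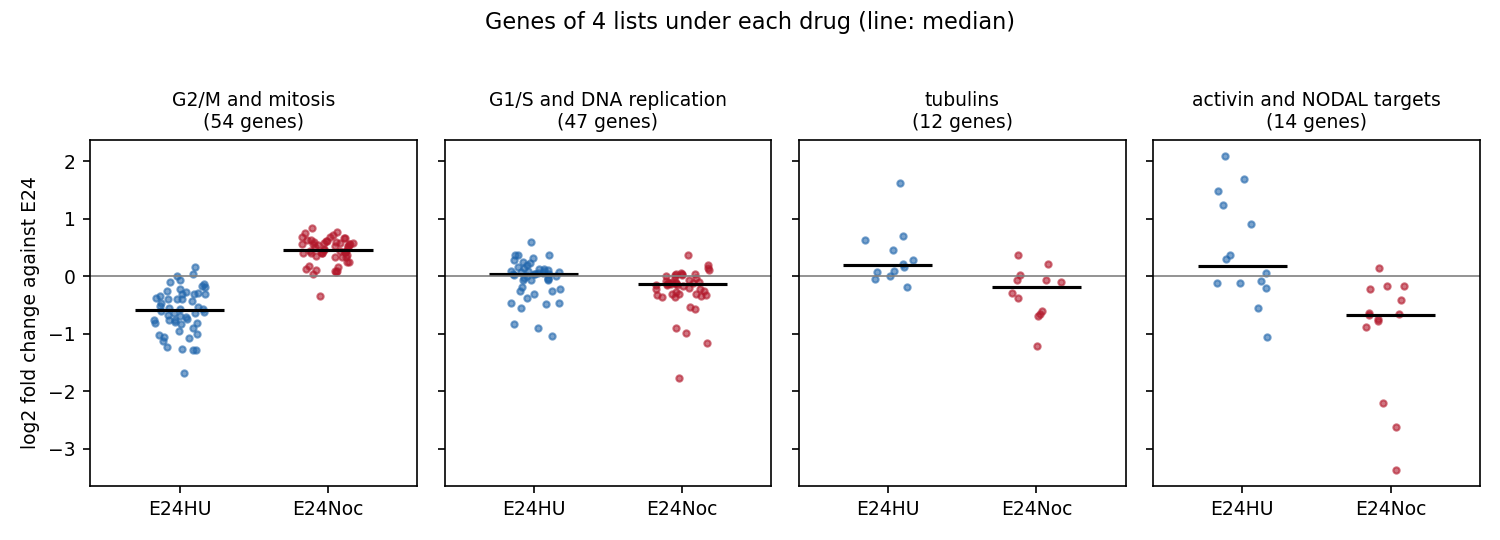
Log2 fold changes against E24 of the genes in 4 lists, under hydroxyurea (E24HU) and nocodazole (E24Noc), with 1 point per gene and a line at the median. Medians were -0.588 and 0.458 for G2/M and mitosis, 0.038 and -0.144 for G1/S and DNA replication, 0.187 and -0.196 for tubulins, and 0.171 and -0.672 for activin and NODAL targets.

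The direct comparison of E24Noc with E24HU tests whether both blocks differ from each other. Mitotic genes were higher under nocodazole: HMMR 4.95-fold (log2 fold change 2.31, SE 0.15, n = 2, adjusted p = 0.00293), PLK1 4.34-fold (2.12, SE 0.12, adjusted p = 0.00293), the spindle kinase AURKA 3.32-fold (1.73, SE 0.12, adjusted p = 0.0031) and BIRC5 (survivin) 2.46-fold (1.3, SE 0.09, adjusted p = 0.0031). CCNE2 was 4.4-fold lower (-2.14, SE 0.19, adjusted p = 0.00544) and EMX2 2.76-fold lower (-1.46, SE 0.1, adjusted p = 0.0031). These 6 genes kept their calls without any 1 of the 8 libraries.

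Of 54 G2/M and mitosis genes, 42 were higher and 1 lower (50 and 1 adjusted over the list alone; median 1.029, list adjusted p = 1.03e-89, and adjusted p = 0.203 with an estimated correlation). Tubulins were lower in 5 of 12 cases and higher in 0 (5 and 0 adjusted over the list alone; median -0.604, list adjusted p = 3.47e-05, and adjusted p = 0.223 with an estimated correlation). TUBB fell by 0.72 and TUBA4A by 1.59. Activin and NODAL targets were lower in 4 of 14 cases and higher in 0 (4 and 0 adjusted over the list alone, 7 and 0 with the block; median -0.69, list adjusted p = 0.000257, and adjusted p = 0.43 with an estimated correlation). They included CER1 (6.66 ± 3.49 against 294.1 ± 158 CPM, log2 fold change -5.46, SE 0.89, adjusted p = 0.0255; chromosome 9, 14719724 to 14722717), GSC (-3.52, SE 0.73, adjusted p = 0.0457) and the NODAL antagonists LEFTY1 (-3.45) and LEFTY2 (-2.15). BMP targets were higher in 1 of 17 cases (1 adjusted over the list alone, 9 with the block; median 1.075, list adjusted p = 4.53e-05, and adjusted p = 0.43 with an estimated correlation). The gene was ID3 (1.17). Definitive endoderm genes were lower in 3 of 15 cases (6 lower and 1 higher adjusted over the list alone, 8 lower with the block; median -0.926, list adjusted p = 0.000436, and adjusted p = 0.371 with an estimated correlation). CXCR4 fell by 1.77. Neuroectoderm genes were lower in 2 of 18 cases (3 lower and 1 higher adjusted over the list alone, 4 lower and 1 higher with the block; median -0.455, list adjusted p = 0.000921, and adjusted p = 0.403 with an estimated correlation). POU3F1 fell by 1.88.

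Other lists passed with all libraries but not without 1 of them, which also unbalances the replicate numbers. With the block all of these passed (list adjusted p = 3.75e-08 to 0.0216, and 0.228 to 0.794 with an estimated correlation too). Called genes were few, given here as lower and higher, with those of the block in brackets. P53 targets had 1 and 0 of 32 (13 and 1), and mesenchymal genes 2 and 0 of 17 (8 and 0). Hypoxia and glycolysis had 0 and 0 of 19 (10 and 1), and immediate early genes 1 and 0 of 17 (5 and 1). Early mesoderm had 1 and 0 of 22 (8 and 2), and epithelial genes 0 and 2 of 19 (1 and 6). Without E24HU replicate 2 some calls ended. These were p53 targets (lower, list adjusted p = 0.000155, then 0.0824, and adjusted p = 0.551 with an estimated correlation), mesenchymal (lower, 0.000511, then 0.0642, and adjusted p = 0.43 with an estimated correlation), and hypoxia and glycolysis (lower, 0.00246, then 0.0524, and adjusted p = 0.371 with an estimated correlation). So did immediate early genes (lower, 0.00479, then 0.214, and adjusted p = 0.43 with an estimated correlation), epithelial (higher, 0.00771, then 0.214, and adjusted p = 0.43 with an estimated correlation) and early mesoderm (lower, 0.0234, then 0.574, and adjusted p = 0.371 with an estimated correlation). Epithelial genes also lost their call without E24Noc replicate 1 (0.099) and early mesoderm without E24Noc replicate 2 (0.0767). Without E24HU replicate 1, calls ended for G1/S genes (lower, 0.0101, then 0.704, and adjusted p = 0.738 with an estimated correlation), primitive streak (lower, 0.0491, then 0.385, and adjusted p = 0.738 with an estimated correlation) and trophectoderm and amnion (higher, 0.0408, then 0.103, and adjusted p = 0.371 with an estimated correlation), and all 3 also ended without E24Noc replicate 2 (0.194, 0.848 and 0.102). The primitive streak call also ended under scaling by library size alone (0.0522). Core histones and H1 passed as higher without E24HU replicate 2 (0.00559), and FOXO targets as lower without E24Noc replicate 2 (0.0391). With all libraries G1/S genes had 4 lower and 0 higher of 47 (10 and 2 with the block). Primitive streak genes had 2 lower and 1 higher of 18 (6 and 2), and trophectoderm and amnion genes 0 and 1 of 12 (1 and 4). CDX2 was 7.19-fold higher (137.2 ± 54.4 against 19.05 ± 7.08 CPM, adjusted p = 0.0198) and NKX1-2 2.8-fold higher, while LHX1 fell by 2.13. Pluripotency genes moved both ways, 3 higher and 3 lower of 21 (3 and 3 adjusted over the list alone, 6 and 6 with the block; median 0.229, mean -0.073, list adjusted p = 0.775). LIN28A rose by 0.52 and SOX2 fell by 1.06.

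In total 664 of 15681 genes differed between the drug groups (324 higher in E24Noc, 340 lower), and 2534 with the replicate block (1120 higher, 1414 lower). The count was 402 and 406 without UD replicate 1 and 2, 327 and 333 without E24 replicate 1 and 2, 91 and 130 without E24HU replicate 1 and 2, 18 and 14 without E24Noc replicate 1 and 2, and 98 with these groups alone. Of the 46 named calls, 40 ended without E24Noc replicate 1, 40 without E24Noc replicate 2, 34 without E24HU replicate 1, 26 without E24HU replicate 2, 15 and 14 without UD replicate 1 and 2, and 9 and 10 without E24 replicate 1 and 2. Their adjusted p then lay between 0.05 and 0.207. CER1, for example, had an adjusted p of 0.0755 without E24HU replicate 1, 0.117 without E24Noc replicate 1 and 0.168 without E24Noc replicate 2.

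**Figure D3:**
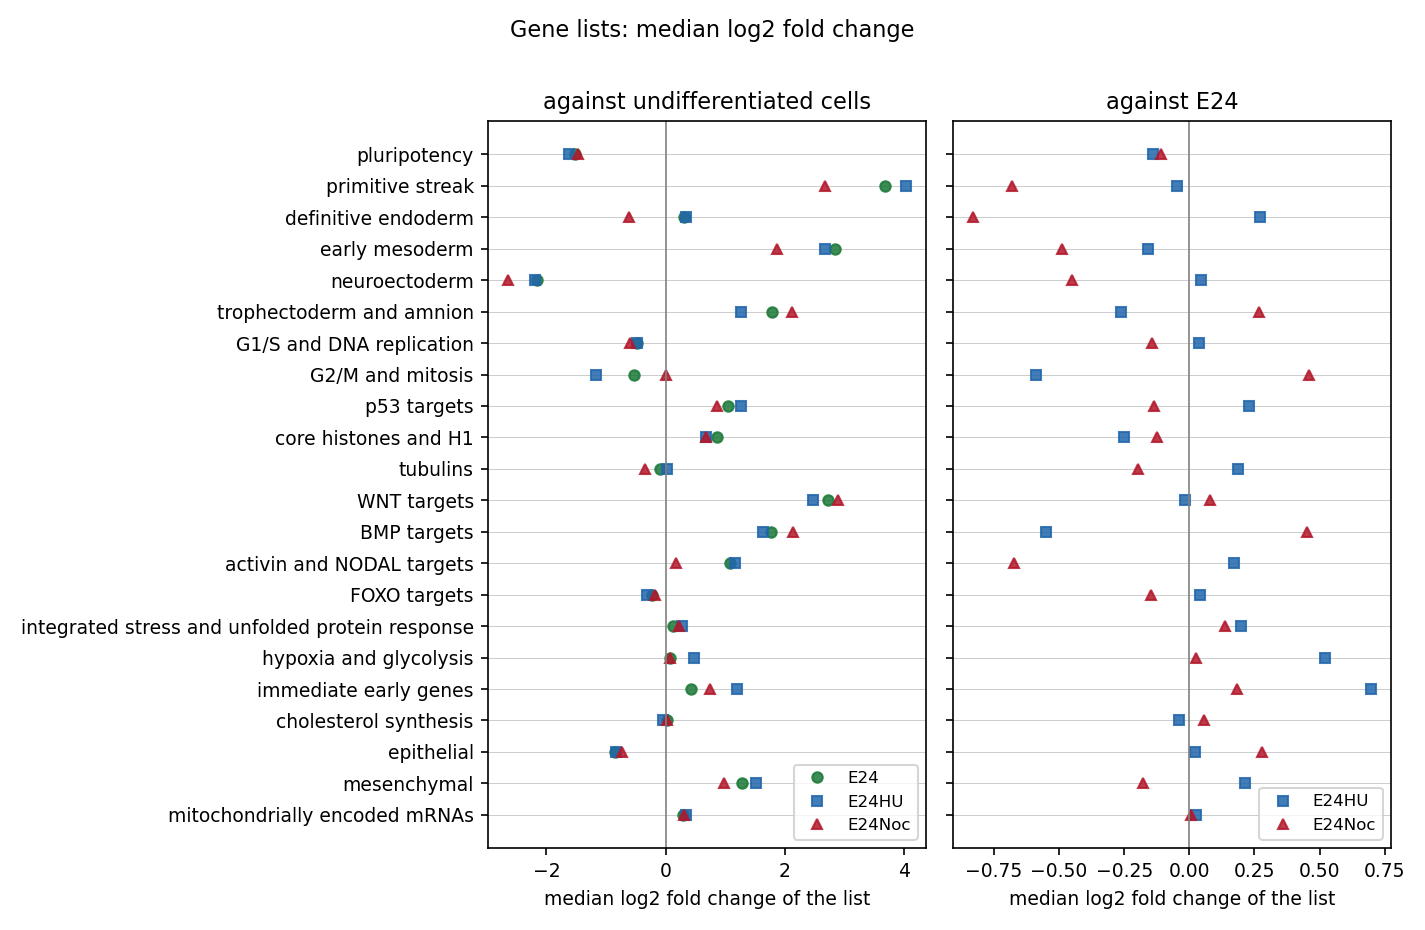
Median log2 fold change of each of the 22 gene lists against UD (circles E24, squares E24HU, triangles E24Noc) and against E24 (squares E24HU, triangles E24Noc). Against UD, primitive streak medians were 3.676, 4.036 and 2.678 and pluripotency medians -1.521, -1.619 and -1.47 in E24, E24HU and E24Noc, while G2/M and mitosis stood at -0.526, -1.169 and 0.004 (-0.094 in E24Noc under scaling by library size).

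Against UD, both drug groups carried the primitive streak and pluripotency changes of differentiation. Early mesoderm genes rose in 14 and fell in 2 of 22 cases in E24HU. In E24Noc 11 rose and 4 fell, and the list call ended without UD replicate 1 or 2. Definitive endoderm genes rose in 4 and fell in 1 of 15 cases in E24HU (6 and 5 with the block, median 0.34, list adjusted p = 0.201). In E24Noc 3 rose and 3 fell (3 and 8 with the block, median -0.607, list adjusted p = 0.462). Under hydroxyurea TBXT was 96.2-fold higher than in UD (log2 fold change 6.59, SE 0.95, n = 2, adjusted p = 0.00331) and MIXL1 98-fold (6.61, SE 1.09, adjusted p = 0.00491). Under nocodazole they were higher 93.6-fold (6.55, SE 0.95, adjusted p = 0.00387) and 69-fold (6.11, SE 1.07, adjusted p = 0.00697). SOX2 fell by 2.37 in E24HU (SE 0.22, adjusted p = 0.00113) and by 3.43 in E24Noc (SE 0.23, adjusted p = 0.000389). Primitive streak genes rose in 15 of 18 cases in E24HU and fell in 0 (15 and 0 adjusted over the list alone; list adjusted p = 1.7e-12, and adjusted p = 0.271 with an estimated correlation). In E24Noc they rose in 10 and fell in 1 (10 and 1 adjusted over the list alone; 2.2e-09, and adjusted p = 0.357 with an estimated correlation). Pluripotency genes fell in 19 of 21 cases in E24HU (19 adjusted over the list alone; 1.68e-13, and adjusted p = 0.257 with an estimated correlation). They fell in 15 in E24Noc (17 adjusted over the list alone; 1.53e-12, and adjusted p = 0.357 with an estimated correlation), and 0 rose in either.

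G2/M and mitosis genes fell in 49 of 54 cases in E24HU and rose in 0 (50 and 0 adjusted over the list alone; median -1.169, list adjusted p = 5.76e-34, and adjusted p = 0.257 with an estimated correlation). HMMR fell by 2.18 and PLK1 by 2.13. In E24Noc, 2 rose and 5 fell (1 and 4 adjusted over the list alone, 6 and 12 with the block; median 0.004, mean -0.061, list adjusted p = 0.665). P53 targets rose in 25 of 32 cases in E24HU and fell in 1 (28 and 1 adjusted over the list alone; 1.23e-14, and adjusted p = 0.299 with an estimated correlation). In E24Noc they rose in 20 and fell in 0 (22 and 0 adjusted over the list alone; 1.06e-08, and adjusted p = 0.391 with an estimated correlation). GDF15 was 13.5-fold higher in E24HU and 3.1-fold in E24Noc. Activin and NODAL targets rose in 9 of 14 cases and fell in 1 in E24HU (9 and 1 adjusted over the list alone; 0.000164, and adjusted p = 0.376 with an estimated correlation). In E24Noc 6 rose and 4 fell (6 and 5 adjusted over the list alone; 0.123). LEFTY1 fell by 3.98 (adjusted p = 0.00686, and 0.0599 without E24Noc replicate 2), and the list passed as higher without UD replicate 1 (0.0107) or E24Noc replicate 2 (0.0154). Immediate early genes rose in 8 of 17 cases and fell in 0 in E24HU (8 and 0 adjusted over the list alone; 6.74e-05, and adjusted p = 0.271 with an estimated correlation). JUNB was 6.83-fold higher. Tubulins rose in 2 and fell in 5 of 12 cases in E24Noc (2 and 5 adjusted over the list alone; 0.0235, and adjusted p = 0.357 with an estimated correlation). The list call was lost with the block (0.0556) and without E24Noc replicate 2 (0.0777). TUBB fell by 0.87 and TUBA1B by 1.03.

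In total 5773 genes differed between E24HU and UD (2910 higher, 2863 lower), with 2777 without UD replicate 1 and 2344 without E24HU replicate 2, and with 2327 higher and 3296 lower under scaling by library size alone. Between E24Noc and UD 5148 differed (2499 higher, 2649 lower), with 2267 without UD replicate 1, 3327 without UD replicate 2, 3116 without E24Noc replicate 1 and 1949 without E24Noc replicate 2, and with 1842 higher and 3033 lower under scaling by library size alone.

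Whether a block returned differentiation genes toward their undifferentiated level was asked of the 2275 genes changed at least 2-fold between E24 and UD. Under hydroxyurea edgeR called 2 of them in E24HU against E24 toward UD and 0 away (292 and 70 at an unadjusted p under 0.05; DESeq2 called 76 and 16), and with the block 104 toward and 33 away of 2752. Under nocodazole edgeR called 0 either way (180 toward and 85 away at an unadjusted p under 0.05; DESeq2 called 56 and 22), and with the block 57 toward and 21 away. Because both contrasts share the E24 libraries, genes picked as high in E24 fall back by chance. Simulations without a drug effect gave a median of 0 called genes each way. At most 2 were toward and 1 away under hydroxyurea. With the block these were at most 1 and 2 under hydroxyurea and 3 and 3 under nocodazole. But with the block the simulations called a median of 1 gene for each drug, against 468 and 243 observed. They therefore cannot show how shared controls split genes with a drug effect into toward and away. The share of genes on the UD side of E24, called or not, was 65.5% under hydroxyurea and 57.7% under nocodazole, against 59.7% (56.6% to 61.1%) and 59.2% (57.3% to 61.7%) in simulations. With the block the shares were 65.2% and 56.4%, against 56.7% (54.5% to 58.8%) and 56.7% (54.3% to 59.0%). The first share was 50.2% without E24HU replicate 1, 76.9% without E24 replicate 1 and 75.9% without E24HU replicate 2. The second was 48% without E24Noc replicate 1 and 75.4% without E24 replicate 1. With genes picked on E24 replicate 1 and compared on replicate 2 the shares were 70.5% and 64.5%, and the other way round 45.7% and 37.8%, but this split leaves the difference between replicate numbers unbalanced. The slope of the E24HU changes against the E24 changes, both from UD, was 0.852 (0.754 to 0.956 over libraries left out) against 0.949 in simulations (0.937 to 0.964), and that of E24Noc 0.93 (0.828 to 0.958) against 0.952 (0.933 to 0.963).

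Whether both blocks changed the same genes was asked of the calls against E24. With edgeR 0 genes passed in both (333 had an unadjusted p under 0.05 in both, 125 in the same direction and 208 in opposite directions; DESeq2 called 49 in both). With the replicate block 41 passed in both, 19 in the same direction and 22 in opposite directions, against 0 and 0 in simulations with shared controls (at most 1 and 0) and 1.57 both higher, 2.02 both lower and 3.67 opposite for independent lists. Genes in both lists with the block, chosen after their values were seen, included the mitotic genes PLK1, AURKA and CCNB1, which were lower in E24HU and higher in E24Noc, and ATF3, a stress-induced transcription factor, which was higher in both (1.04 and 0.96, adjusted p = 0.0154 and 0.0273 with the block). Part of the excess in the same direction may come from the shared controls acting on genes with a drug effect. The simulations held no such effect, and 2 libraries are too few to split. In simulations with the block, shared controls gave 66.7% of genes the same sign, so they push both contrasts the same way. At most 0 were called in opposite directions. That count cannot decide, as the simulations called a median of 1 gene for each drug. The share of signs argues against shared controls as the source of the 22 opposite genes. Across genes the covariance of both sets of fold changes was -0.007 against 0.037 in simulations, and 48.2% of genes had the same sign against 66.9% in simulations.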

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

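The tests of slower differentiation, of reads shared between actin genes, of more undifferentiated cells and of a shift toward BMP targets were chosen only after the result was seen. In total 12 genes were picked out because their response to differentiation differed between both drugs, by the test of E24Noc against E24HU. Higher under nocodazole were EBF3 (log2 fold change 3.19), CDX2 (2.85), FILIP1L (2.67), HMMR (2.31), ANXA3 (2.23) and PLK1 (2.12). Lower were CER1 (-5.46), CYP26A1 (-4.38), SELE (-3.64), GSC (-3.52), LEFTY1 (-3.45) and NOS2 (-3.05). HMMR and PLK1 kept their calls without any 1 library. CYP26A1 and GSC lost theirs under scaling by library size, and CYP26A1, GSC, LEFTY1, NOS2 and SELE with limma-voom.

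Activin and NODAL targets were lower under nocodazole than under hydroxyurea as a list, with 4 of 14 called (list adjusted p = 0.000257, adjusted p = 0.43 with an estimated correlation, and 0.0998 with that and the block). A difference between the replicate numbers is argued against, because 10 of 14 genes were lower within both numbers and 1 was higher within both. The test of slower progress of differentiation cannot decide, as it sets nocodazole against hydroxyurea and not against E24. The 1413 genes that fell from UD to E24 were lower under nocodazole than under hydroxyurea (median -0.276, and -0.332 and -0.2 by number). A delay would leave them higher. The 862 genes that rose were lower too (-0.061 and -0.301), as a delay would have it. But under hydroxyurea 65.5% of differentiation genes lay on the UD side of E24, against 59.7% in simulations. Such a shift alone could leave the fallen genes higher there. Against E24, 57.7% of differentiation genes lay on the UD side under nocodazole, within the 57.3% to 61.7% of simulations. The slope of 0.93 lay just below their range (0.933 to 0.963). With 1 library left out the share ran from 48% to 75.4%, so a delay under nocodazole stays undecided. A move of nocodazole-treated cells along the direction in which the replicate numbers differ cannot be told apart from a drug effect on these targets, since the correlation across 13083 genes was 0.134 and lay between both bounds set for the test (0.141 without the cell cycle lists, Spearman -0.009). A direct action of nocodazole on the pathway, its later start at 8 h and the arrest itself were not tested.

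CNN1 and ACTA1, genes of the actin cytoskeleton, were higher under nocodazole than in E24. A list made afterwards of 30 targets of SRF and its cofactor MRTF, without the genes that raised the question, had a median of 0.496 with the replicate block (0.546 and 0.449 by number; camera p = 7.53e-30, and p = 0.0133 with an estimated correlation), as a response of these targets needs. Without the block edgeR called 0 of the 30 over all genes (15 higher and 1 lower unadjusted, DESeq2 7 higher, limma-voom 0) and 11 higher over the list alone, and the camera p was 1.39e-17, and p = 0.0536 with an estimated correlation. Whether more cells in mitosis were the source could not be decided. The same list had a median of 0.2 under hydroxyurea (0.145 and 0.236), where G2/M genes were lower. But immediate early genes were higher there (median 0.698), so other effects of hydroxyurea could hide a fall. In E24Noc the arrest and other actions of the drug cannot be told apart. The test of reads shared between actin genes cannot decide on ACTA1, which was not in the list. Leaving out ACTA2 and ACTG2 could hardly move a median over 30 genes. The other 28 targets had a median of 0.496, so the rise of the list did not rest on reads of these actin genes. A response of SRF targets to the drug stays a hypothesis found and tested on the same libraries.

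Libraries numbered 1 and 2 differed in fate genes in every group. Unequal depth is argued against, as the deeper library had the higher primitive streak median in 2 of 4 groups. Pluripotency genes were lower in number 2 (-0.479, the median over genes of the mean of the 3 differentiated groups, and medians of -0.45, -0.575 and -0.403 in E24, E24HU and E24Noc). More undifferentiated cells in number 2 would raise them. They were lower in number 2 in UD as well (-0.364). The 3 differentiated medians lay below that value, so an offset of that size does not hide a rise. On the first principal component, which parted UD from the rest, the libraries numbered 2 lay further from UD. They stood at 45.53 against 19.19 for number 1 in E24, 39.66 against 8.19 in E24HU and 41.5 against 26.08 in E24Noc. Primitive streak genes were lower in number 2, but in UD too. The pluripotency and component values argue against more undifferentiated cells in number 2. A shift from activin and NODAL targets to BMP targets and extraembryonic genes stays open: over 23 genes of the second kind the same value was 0.576, but the medians were 0.53, 1.136 and 0.131 by group, and over 12 activin and NODAL targets it was -0.551 (medians of -0.56, -0.484 and -0.462). The labels give no day or batch for the numbers, so a difference between days cannot be told apart from such a shift.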

How the results depend on the processing

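DESeq2 with the replicate block, the block without the UD libraries and the block with an estimated correlation were chosen only after the data were seen. Each group held 2 libraries, so counts of genes depended on the spread that the fit assumed, and pairing by replicate number rested on the data alone. Counts for E24, E24HU and E24Noc against UD stayed within 1.5 times under every setting but a left-out library. For E24HU against E24 the 6 genes became 0 with library size alone, 10 with no filter, 394 with DESeq2, 0 with the compared groups alone, 468 with the block, 1369 with DESeq2 and the block, and 2458 with the block without UD. For E24Noc against E24 the 4 genes became 10 with no filter, 269 with DESeq2, 0 with the compared groups alone, 243 with the block, 849 with DESeq2 and the block, and 1386 with the block without UD. For E24Noc against E24HU the 664 genes became 1672 with DESeq2, 98 with the compared groups alone, 2534 with the block, 3276 with DESeq2 and the block, and 4879 with the block without UD. Differentiation genes moved back under hydroxyurea (2) became 0 with library size alone, 76 with DESeq2, 104 with the block, 245 with DESeq2 and the block, and 0 when picked with E24 replicate 1 or with E24 replicate 2 (0), where no other count was open, since fits without an E24 library called 0 genes. Under nocodazole (0) they became 2 with no filter, 56 with DESeq2, 57 with the block and 144 with DESeq2 and the block. Genes shared by both drugs (0) became 49 with DESeq2, 41 with the block, 230 with DESeq2 and the block, and 482 with the block without UD. The cause was not tested.

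Lists that passed (13 in E24 against UD, 7 in E24HU against E24, 14 in E24Noc against E24, 15 in E24HU against UD, 14 in E24Noc against UD and 15 in E24Noc against E24HU) became 0 in each of the 6 with an estimated correlation. With the block and an estimated correlation they became 1, 0, 0, 1, 0 and 0, and the list that passed was pluripotency both times (adjusted p = 0.0458 and 0.0427). The cause was not tested. The block ended 3 list calls given in the report and, beyond the added ones given there, it added definitive endoderm in E24HU against UD (adjusted p = 0.0287) and trophectoderm and amnion in E24Noc against UD (0.0462). It ended no gene call and changed no other list call.

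With 1 library left out, where the lone library of a group was assumed to vary like the other groups, the counts ranged from 1300 to 4682 for E24 against UD, 0 to 0 for E24HU against E24, 0 to 5 for E24Noc against E24, 2344 to 5337 for E24HU against UD, 1949 to 4925 for E24Noc against UD and 14 to 406 for E24Noc against E24HU. Genes moved back ranged from 0 to 0 for each drug and genes shared by both drugs from 0 to 0. Lists ranged from 12 to 16, 7 to 9, 9 to 15, 13 to 17, 11 to 15 and 10 to 15 in the order given above. Of 8711 values for the named genes under other settings, 7928 kept their call or, if called under neither setting, stayed within the SE of the main value. A further 541 were no longer past the threshold and 119 came past it. Another 123, called under neither setting, moved by more than that SE. Among values called in the main fit or under the other setting, 0 turned direction, and turns among the rest were not counted. At 74.31 M reads or more per library, genes such as VTCN1 had 0 to 3 reads in the differentiated libraries, and the effect of depth was not tested.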

Other observations

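The list of SRF targets and the replicate differences were examined only after the first results were seen, and their genes were chosen after their values were seen. Of 30 SRF targets, 28 had a positive log2 fold change in E24Noc against E24, and 14 rose and 0 fell with the replicate block, while without the block edgeR called 0 over all genes and 11 were higher adjusted over the list alone. At an unadjusted p under 0.05, 15 were higher and 1 lower, and DESeq2 called 7 higher and limma-voom 0. TAGLN, an actin-binding protein of smooth muscle, rose by 1.05 (adjusted p = 0.0138 with the block), VCL, the focal adhesion protein vinculin, by 0.65 (0.0213), MYL9, a myosin light chain, by 0.68 (0.0253), and ANKRD1, also a target of YAP, by 1.42 (0.0365). SRF itself rose by 0.57 (0.0366).

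In the blocked fit 1539 of 15681 genes differed between replicate numbers (840 higher in number 2, 699 lower). Activin and NODAL targets had a median log2 difference, number 2 minus number 1, of -0.407 in UD, -0.828 in E24, -0.837 in E24HU and -0.677 in E24Noc. BMP targets stood at -0.193, 0.543, 1.552 and 0.163, trophectoderm and amnion genes at -0.186, 0.764, 0.459 and 0.378, and p53 targets at 0.238, 0.461, 0.434 and 0.297 in the same order.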
